A study of Quercus robur with 96 samples.

How the data were processed

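Leaves of the second growth cycle of pedunculate oak (Quercus robur) microcuttings were sampled in 16 groups of 3 biological replicates, per the labels. The groups crossed 2 growth stages (shoot flush, SF, and root flush, RF) with 2 inoculations (Co, none, and Pc, the ectomycorrhizal fungus Piloderma croceum). Each of these 4 combinations, called strata here, held 4 herbivory treatments with caterpillars of Lymantria dispar. The treatments were no damage (none), damage in the second cycle only (trig), damage in the first cycle only (prim) and damage in both cycles (primtrig). Each biological replicate was read in 2 technical replicates, which gave 96 deposited samples for 48 biological replicates.

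The deposited raw table held threshold cycles (Ct) of a microfluidic quantitative PCR with EvaGreen after 18 cycles of preamplification, per the labels' protocols. Of its 6240 cells 124 were empty, and Ct ran from 2.5 to 24.09. The deposited normalized table held a ratio: per the file headers the authors averaged the 2 technical replicates and normalized them to the 18S ribosomal RNA gene. Of its 3120 cells 20 were empty (0.641%), and 54 of the 65 assays were measured in all 48 biological replicates. How a Ct was called is not given in the sources used here. The 18S Ct were not among the values used here and were computed as mean Ct plus log2 of the normalized value, which was 1 constant per sample for 64 of the 65 assays. For those 64 assays 0 values lay over 0.2 cycles from that constant, and the largest difference was 0.11 cycles. For PRX1 38 of 41 comparable values lay over 0.2 cycles away and 7 values were in only 1 table, so its values are uncertain and PRX1 is named below only where the naming rule asked for it. The authors' deposited fold changes were ratios of arithmetic means of 3 normalized values over the undamaged, uninoculated group of the same stage, per the file headers. All 910 of these ratios were recomputed within 0.18%, with the denominator of the shoot flush group read as its 3 biological replicates.

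Assays carried a short name, a description and an identifier, of which 27 were Qrob gene models and 38 were transcript assembly identifiers. Of these identifiers 0 matched the reference table of gene symbols, so names and functions are those of the deposited tables. No genome was used and no coordinates are given.

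The normalized ratios were log2-transformed here, so that a change of 1 is a 2-fold change, and no value was filled in for limma. The deposited 2-replicate means were kept, which leaves 1 value per biological replicate. All 48 replicates entered 1 group-means model per assay in limma 3.58.1 (R 4.3.3) with 32 residual degrees of freedom, and each comparison was a contrast of that model. Assays needed 2 measured replicates in each group of a comparison, which left 64 or 65 assays. P-values were two-sided, came from limma's moderated test, were adjusted by the Benjamini-Hochberg method over the assays of the comparison, and counted as passed at an adjusted value under 0.05. They measure the spread between biological replicates. A value given with ± is the change with its standard error from limma, unless a standard deviation (SD) is named. The mean of 4 strata is the average of the 4 within-stratum changes, and the direction counts say how many of the treated replicates lay beyond the mean of the comparison group of their own stratum.

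The comparisons, tests, named genes and first alternatives were chosen before the data were examined. The naming rule took every gene that passed in a comparison when 25 or fewer did, otherwise the 25 with the smallest adjusted p. For the 4 herbivory contrasts averaged over strata it added, for each fixed list, the member with the largest absolute change. The lists with members in this panel were jasmonate, salicylate, ethylene, abscisic acid, auxin and gibberellin, phenolics, terpenoids and volatiles (6 farnesene synthases and 6 hydroperoxide lyases), defence proteins, redox, transcription factors, and photosynthesis and carbon. Laccases and the multicopper oxidase were grouped after the data were seen. Lists of at least 3 members, which were 7, were tested with limma's fry, which tests whether the genes of a set move on balance in the same direction and does not compare the set with other genes. For fry alone, missing values took the mean of their group.

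The alternatives fixed at the start were centring each sample on the median Ct of the 54 complete assays in place of 18S, missing values set 1 cycle beyond the highest Ct of the assay, and complete assays only. They also held a fit of the contrast's own groups, the replicate number as a block, both technical replicates kept with a duplicate correlation (0.958), and leaving out each replicate in turn. Alternatives chosen after seeing the data left out RF_Co_primtrig replicate 2, SF_Co_none replicate 1 or PRX1, blocked the SF_Co groups alone, or centred on the median of all measured assays. Damage in both cycles against first-cycle damage only, root flush against shoot flush averaged over 8 pairs of groups, and 24 interaction contrasts were also added after seeing the data. The numbers of the replicates did not pair samples in general. After subtracting group means, the mean correlation over assays was 0.025 between same-numbered replicates of different groups and -0.015 between differently numbered ones. All 3 same-numbered pairs correlated over 0.1 in 4 of 16 within-stratum comparisons, all of them in SF_Co (0.11 to 0.92), and the blocked counts are given there.

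The self-test shifted 20 assays in data simulated from the spread of these samples, 40 data sets per size. Each simulated sample drew its deviations from any of the 48 replicates, so all simulated groups had the same expected spread. The real groups did not, as for MCO with an SD of 6.447 in SF_Co_none and 0.9477 in SF_Co_trig. The rates for SF_Co need therefore not hold for its own spread. For triggered against undamaged leaves in 1 stratum (SF_Co, 65 assays), limma recovered 8.6% of the shifted assays at a log2 change of 2, 35% at 3 and 57% at 4. For the mean of 4 strata (65 assays) it recovered 11% at 1, 62% at 2 and 91% at 3. For the inoculation contrast over 8 pairs (64 assays) it recovered 27% at 1 and 91% at 2. With no shift, 1, 2 and 0 of the 40 data sets had any call in these 3 designs. The mean number of false calls per data set was then 0.35, 0.8 and 0, so the few data sets with a call held many at once. Over 4 strata the mean was 1.9 at a log2 change of 2. fry called a shifted volatiles list in 21 of 40 data sets at a change of 1 and in 40 at 2, and 1 of 40 with no shift. Calls of the other 6 lists, which were not shifted, numbered 8 and 12 over these 40 data sets and 5 with no shift.

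Over assays, the difference between the technical reads of a sample had a median SD of 0.131 cycles, and that between biological replicates of the same group 1.67. The smallest SD between biological replicates of the same group was 0.296, so no sample was a copy of another of its group. Pairs across groups were not compared in this way. 1 technical read, of RF_Pc_prim replicate 2, was empty throughout. No processing batch, plate or date is given in the sources used here, so none could enter the model.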

Results

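Transcripts of 65 assays were measured by quantitative PCR in oak leaves that had or had not been fed on by caterpillars of the moth Lymantria dispar. The panel held enzymes of the jasmonate pathway, farnesene synthases and hydroperoxide lyases that make leaf volatiles, hormone genes, pathogenesis-related proteins and laccases. The 48 biological replicates fell into 16 groups of 3, by growth stage, fungal inoculation and herbivory in the first, the second, both or neither of 2 growth cycles. Levels relative to 18S spanned 1.78e-06 to 2.6. The first component of all samples held 70.9% of the variance and the next ones 11.5%, 6.82% and 4.18%. The 18S Ct lay between 3.88 and 5.99 in 47 replicates and at 9.44 in the remaining one, RF_Co_primtrig replicate 2, whose profile also stood apart. That replicate was kept, and results that rested on it are given without it as well.

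**Figure D1:**
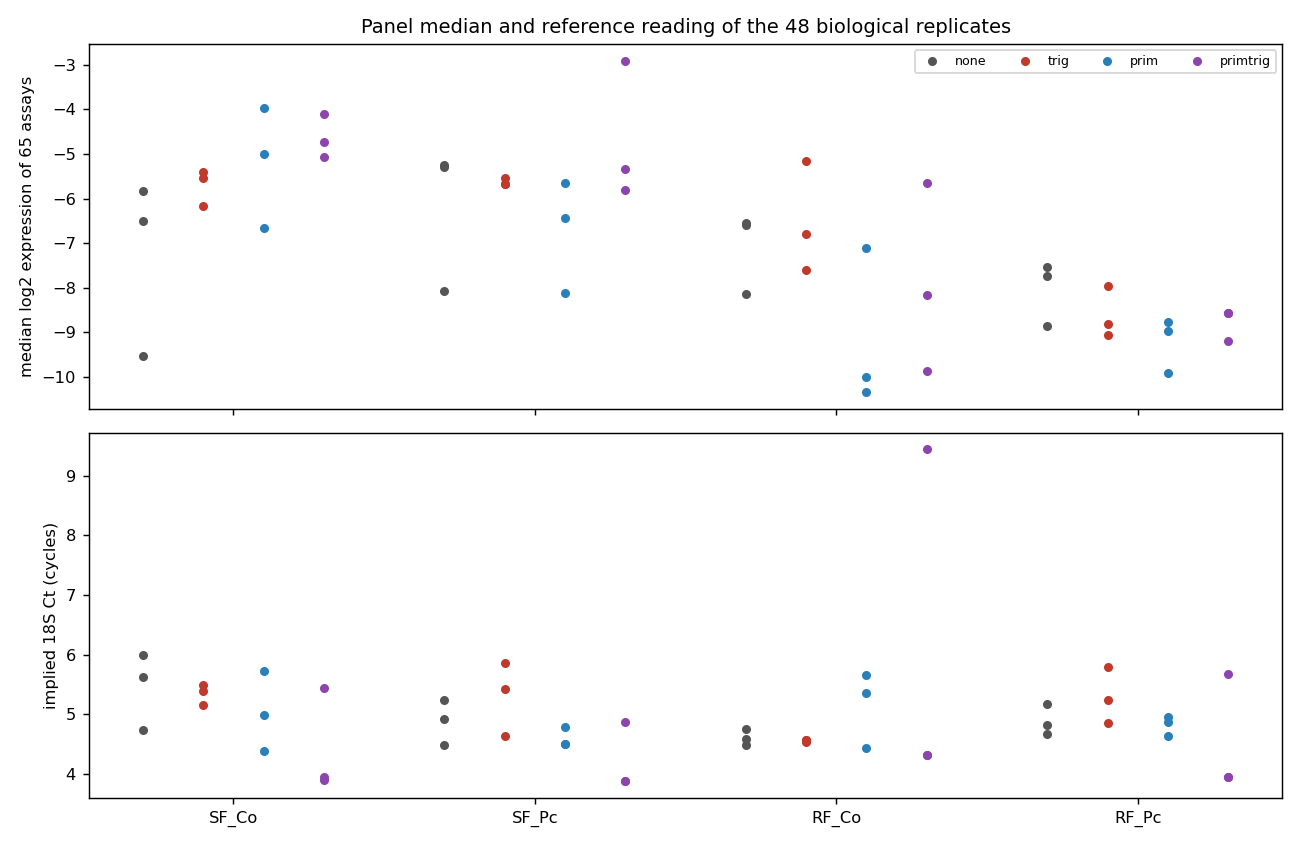
The upper panel shows the median log2 expression relative to 18S over the assays of each biological replicate, the lower panel the 18S Ct in cycles computed from the deposited tables. Points are the 48 replicates, coloured by herbivory treatment, and RF_Co_primtrig replicate 2 lies at 9.44 cycles, above the 3.88 to 5.99 of the other 47.

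Caterpillar feeding in the second cycle alone raised transcripts of enzymes that make leaf volatiles. Hydroperoxide lyases cleave fatty acid hydroperoxides into green leaf volatiles, and HPL3 (Qrob_P0010740.2) rose by 3.01 ± 0.795 on the log2 scale, from -10.90 to -7.89 on average over 4 strata. Of the 6 alpha-farnesene synthases, which make a volatile sesquiterpene, 3 rose as well, among them FAR5 (Qrob_P0119260.2) by 2.53 ± 0.689 and FAR6 by 2.00 ± 0.612. TAN (comp44155_c0_seq1), described in the deposited table as a tannin transcription factor, rose by 2.49 ± 0.742. FAR4 (2.53), HPL4 (2.04), HPL6 (2.02), HPL5 (1.99) and HPL2 (1.99) completed the 9 genes that passed, and 0 genes fell. Their adjusted p ran from 0.0162 for HPL3, FAR4 and FAR5 to 0.0312 for the other HPL genes. The change was seen in 12 of 12 triggered replicates for FAR4 and FAR5, 11 of 12 for the 5 HPL genes, 10 for FAR6 and 9 for TAN. FAR4 and FAR5 followed each other within read noise. HPL2, HPL4, HPL5 and HPL6 followed each other closely, though not within it (SD of the pair differences 0.13 to 0.29). These calls are therefore fewer than 9 separate observations. Without replicate 1 of each group, and likewise without replicate 2, 0 genes passed, and without SF_Co_none replicate 1 alone 4 did.

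Of the 12 genes in the terpenoids and volatiles list 8 rose, also 8 when adjusted over the list alone, with a median change of 2.00 and a fry false discovery rate (FDR) of 0.00165. That list did not pass with technical replicates kept (FDR 0.105), on the median of all measured assays (0.184) or on the panel median (0.205), where auxin and gibberellin moved down instead (0.0278). In the jasmonate pathway, whose enzyme AOS shares hydroperoxides with the lyases, AOC, which acts after AOS, was 1.36 ± 0.586 higher (10 of 12 replicates, adjusted p 0.165) and 0 of 5 genes passed, 0 also adjusted over the list alone. FAR1 and FAR3 did not pass (-1.10 and -1.11), nor did FAR2 (1.44) or HPL1 (0.24). Among the 14 defence proteins PRX5 moved most, by 0.90 ± 0.772 (adjusted p 0.778, 9 of 12). In the other lists the largest changes were PAL 0.81 (phenolics, adjusted p 0.358), NCED2 0.77 (abscisic acid, 0.742), SOD -0.37 (redox, 0.961), ICS2 -0.30 (salicylate, 0.961), IAA3 -0.26 (auxin and gibberellin, 0.961), HEX 0.12 (photosynthesis and carbon, 0.961) and ETH -0.03 (ethylene, 0.979). Of the members of these 8 lists 0 passed, also 0 when adjusted over each list alone, and of the 3 transcription factors TAN passed on both counts. Relative to 18S no other list than volatiles passed fry, with an FDR of 0.855 for jasmonate and 0.978 for defence proteins.

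The reference mattered for these calls. Centring on the panel median in place of 18S lowered the changes by 0.578, which moved the split from 41 genes higher and 24 lower to 24 higher and 41 lower. TAN (1.92, adjusted p 0.00698) and HPL3 (2.43, adjusted p 0.0385) passed on both scales. FAR4, FAR5, FAR6 and the other HPL genes with a call stayed higher (1.41 to 1.96) without passing, with smaller changes and, for FAR5, an SE of 0.886 in place of 0.689. Over the panel, in contrast, the median SE was smaller on that scale, 0.464 in place of 0.654. On that scale 8 genes were lower with a call: GRAS2 (-1.16), GRAS1 (-1.02), PER31 (-1.19), DRP, THAU1 (-0.93), GLU1 (-1.39), IAA3 and MAD2, which were chosen for naming after their values were seen.

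Within single strata FAR5 was 4.70 ± 1.38 higher after second-cycle feeding in SF_Co, 3.05 in SF_Pc, 1.71 in RF_Co and 0.65 in RF_Pc. HPL3 was higher by 2.99, 2.77, 2.14 and 4.13 in the same order, each with an SE of 1.59. TAN was higher by 4.27, 1.29, 1.54 and 2.88. In limma 0 genes passed in any of the 4 strata, while 8, 4, 0 and 2 had an unadjusted p under 0.05. In SF_Co FAR4 and FAR5 had the smallest adjusted p, 0.0505, with 3 of 3 replicates higher. They passed, as 2 calls, with the replicate number as a block, and FAR4, FAR5, FAR6 and TAN passed as 4 calls when the SF_Co groups alone were fitted with that block. Without SF_Co_none replicate 1 there were 2 calls, and without SF_Co_trig replicate 2 there were 3. The stages were not shown to differ in this response (0 genes with an interaction in limma, smallest adjusted p 0.994, 1 at an unadjusted p under 0.05). That 1 was FAR6, whose change was lower at root flush by 3.09 ± 1.22 (unadjusted p 0.0158 in limma). FAR6 was higher by 3.74, 3.36, 0.825 and 0.09 in the order of strata above. FAR5, FAR4 and FAR2 followed, with interactions of -2.69, -2.69 and -3.28 (unadjusted p 0.0582 to 0.0612). FAR1 and FAR3 went the other way (0.92 and 0.96). The inoculations were not shown to differ either (0 genes, smallest adjusted p 0.707, 0 unadjusted). Centring on the panel median raised the stage and inoculation interactions by 1.05 and 1.06 and gave 0 and 1 calls, the latter CHI_II.

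**Figure D2:**
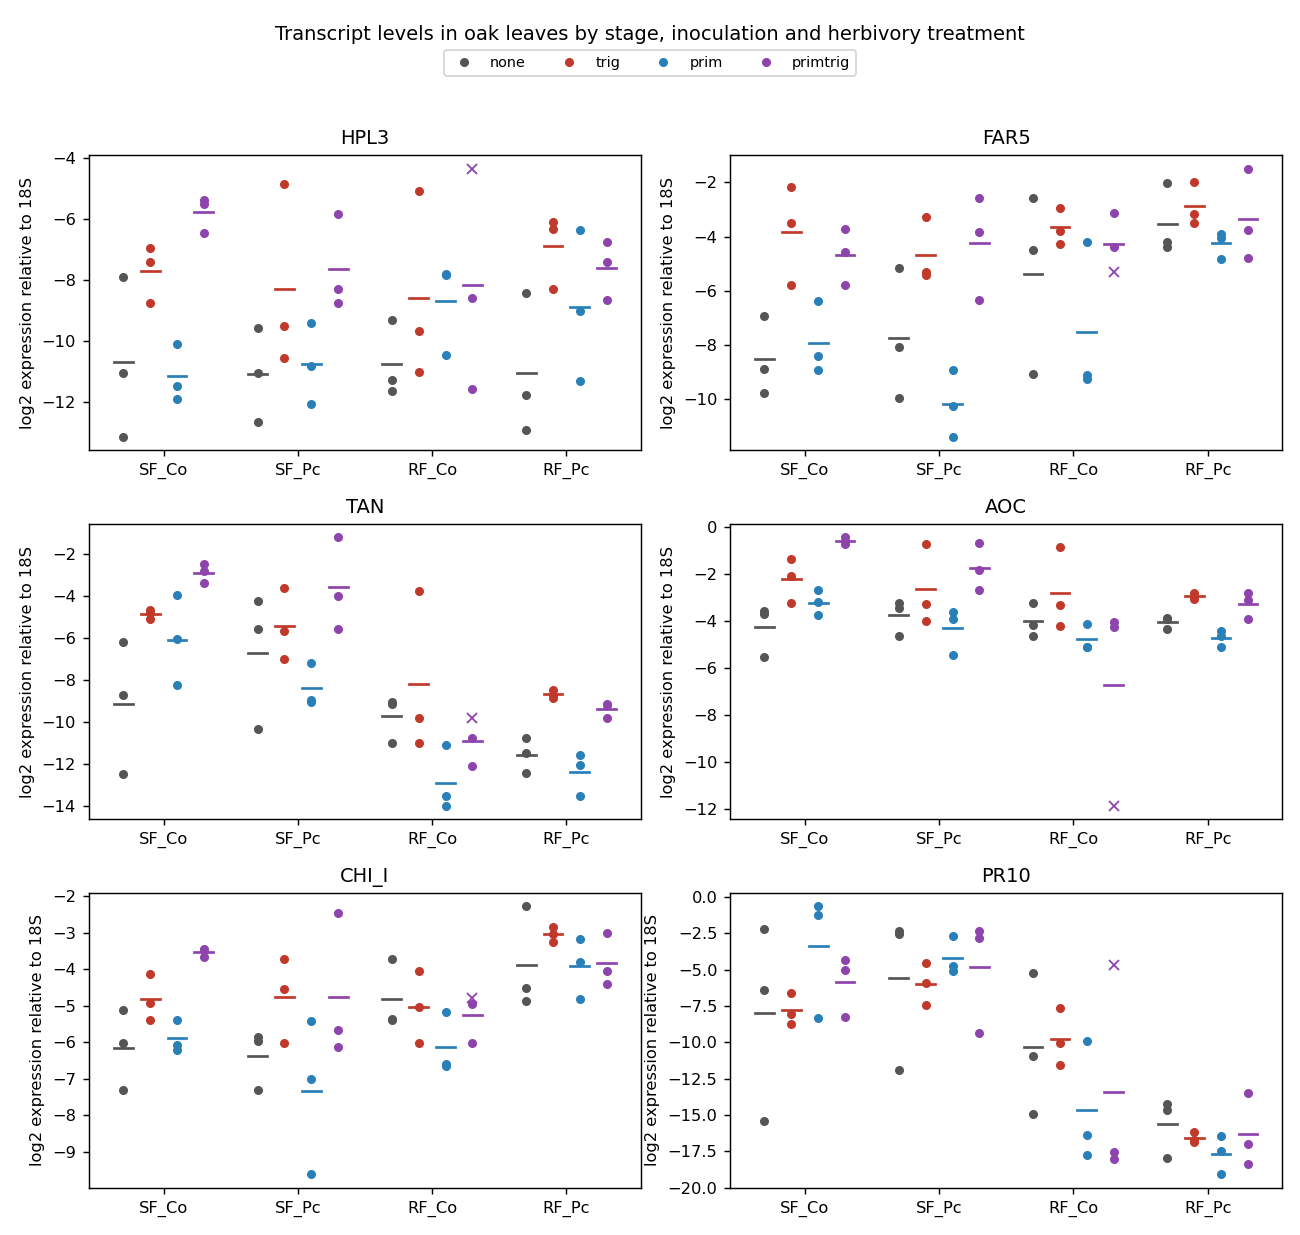
Log2 expression relative to 18S of 6 assays in the 16 groups, with a point per biological replicate (3 per group), a line at the group mean, and a cross for RF_Co_primtrig replicate 2. HPL3 and FAR5 lay higher in triggered than in undamaged leaves on average over 4 strata by 3.01 and 2.53, and the change of PR10 from shoot flush to root flush was -8.59 over 8 pairs of groups.

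Feeding in the first cycle alone left no gene of the second-cycle leaves with a call. The farnesene synthase FAR2 differed by -2.25 ± 0.848 on average over 4 strata, in 11 of 12 replicates (adjusted p 0.252). The lipoxygenase 13LOX3 (Qrob_P0338490.2), which oxidizes fatty acids at the head of the jasmonate and lyase pathways, was 2.83-fold lower, with a log2 SE of 0.594 (8 of 12, adjusted p 0.252). NCED1, which makes an abscisic acid precursor, differed by -1.46 (7 of 12, 0.309), and superoxide dismutase SOD by -1.23 (8 of 12, 0.347). The remaining list members named by the rule lay between -0.98 for ICS2 and -0.17 for IAA3, with ETH at -0.86, GLU2 at -0.84, GRAS2 at -0.71, ERD6 at -0.52 and PAL at -0.24. In limma 0 of 64 genes passed, with 9 at an unadjusted p under 0.05, and 0 of 7 lists passed fry (smallest FDR 0.221, for jasmonate and abscisic acid). Adjusted over the list alone, the only call was SOD, the sole member of its list. The panel leaned lower relative to 18S (13 genes higher, 51 lower). Centring on its median, which by construction removes a shared lean, raised changes by 0.429 (30 higher, 34 lower). Without replicate 3 of each group 14 genes passed, all lower, among them 13LOX3, SOD and NCED1.

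Per stratum, the panel median after first-cycle feeding differed from undamaged leaves by 1.47 in SF_Co, -0.448 in SF_Pc, -2.14 in RF_Co and -1.34 in RF_Pc. In limma 0 genes passed in each, with 4, 0, 17 and 0 at an unadjusted p under 0.05, and 0 also in SF_Co with the replicate block. The RF_Co result rested on RF_Co_prim replicate 3, without which 42 genes passed, 38 of them lower. The difference between stages in the uninoculated plants had 0 genes with an interaction in limma, 35 at an unadjusted p under 0.05, and a smallest adjusted p of 0.0654. Without RF_Co_primtrig replicate 2 in the shared spread, 20 genes passed that test, all with a lower change at root flush, and on the median-centred scale 0 did.

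Feeding in both cycles raised 5 of the 6 hydroperoxide lyases above undamaged leaves. HPL3 rose by 3.59 ± 0.795 and HPL4 (Qrob_P0010750.2) by 2.99 ± 0.651, a 12.1-fold and a 7.92-fold increase averaged over 4 strata. HPL6 rose by 2.97, HPL2 by 2.93 and HPL5 by 2.91, while HPL1 (-0.29, adjusted p 0.846) did not pass. TAN rose by 2.60 ± 0.742, and the farnesene synthases FAR5, FAR4 and FAR6 by 2.15, 2.15 and 1.81. The adjusted p was 0.000924 for the 5 lyases, 0.0127 for TAN, 0.0291 for FAR4 and FAR5 and 0.0382 for FAR6. The direction was shown by 12 of 12 replicates for HPL2 and HPL6, 11 for HPL3, HPL4 and HPL5, 10 for the farnesene synthases and 9 for TAN. The same 9 genes passed after second-cycle feeding alone, but both comparisons use the same undamaged leaves, so the overlap is not independent evidence. In the volatiles list 8 of 12 rose, 8 also adjusted over the list alone, with a fry FDR of 0.000176 relative to 18S and 0.125 on the median-centred scale.

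NCED2 was 1.66 ± 0.630 higher without passing (9 of 12, adjusted p 0.0719). AOC (0.94), SA (0.45), FLAVO1 (1.21), PRX1 (1.39, an assay whose deposited tables disagree), HEX (0.44) and ETH (0.26) were higher and SOD (-0.71) lower without passing. Their adjusted p ran from 0.199 for PRX1 to 0.863 for ETH, and 0 jasmonate genes passed, also 0 adjusted over the list alone. The median-centred scale lowered changes by 0.672 (45 higher and 20 lower became 27 and 38). It kept 6 of the 9 calls, TAN and HPL2 to HPL6, with 1 more gene higher and 7 lower. Leaving out replicate 1 of every group left 5 calls, the HPL genes.

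In SF_Co, damage in both cycles was associated with 15 genes higher and 0 lower than undamaged leaves. TAN rose by 6.25 ± 1.48, from -9.15 ± 3.17 (SD, n = 3) to -2.90 ± 0.446 (SD, n = 3). The multicopper oxidase MCO rose by 7.77 ± 2.59 and the laccases LDO and LACP1, which oxidize phenolic compounds, by 5.48 and 3.97. AOC (Qrob_P0758490.2), a jasmonate enzyme, rose by 3.68 ± 1.17, the chitinase CHI_I by 2.62 and the phenylpropanoid enzyme PAL by 2.50. HPL3 (4.91), HPL4 (4.79), HPL5 (4.77), HPL6 (4.60), HPL2 (4.54), FAR5 (3.84), FAR4 (3.82) and FAR6 (3.35) also rose. The adjusted p ran from 0.00948 for TAN to 0.0471 for PAL, and 3 of 3 replicates were higher in each. Adjusted over the list alone, 8 volatiles genes, 1 jasmonate gene and 0 defence proteins passed. With the replicate number as a block 17 genes passed, and 22 when the SF_Co groups alone were fitted with it. Far fewer than 15 passed in a fit of the contrast's own groups, as given below. The calls rested on few replicates. Without SF_Co_none replicate 1, or without SF_Co_primtrig replicate 3, 0 genes passed, without SF_Co_primtrig replicate 1 or replicate 2 it was 1 or 5, and without SF_Co_none replicate 2 it was 9. Centring on the panel median lowered changes by 2.63 (62 higher and 3 lower became 21 and 44), left TAN higher and GRAS1 lower with a call, and turned CHI_I and PAL to -0.0092 and -0.13.

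In the other strata limma called 0 genes for damage in both cycles against none, with 9 in SF_Pc, 5 in RF_Co and 1 in RF_Pc at an unadjusted p under 0.05. FAR6 passed in SF_Pc without SF_Pc_none replicate 1. In RF_Co, CALI, AOS, 13LOX3, AOC and HPL1 passed as lower without RF_Co_primtrig replicate 1, when the atypical replicate 2 made up 1 of the 2 left. The change in uninoculated plants differed between stages for 5 genes, each with a lower change at root flush: LDO by -8.80, TAN by -7.41, AOC by -6.39, LACP1 by -6.03 and 13LOX3 by -5.87 (adjusted p 0.0264 to 0.036). These 5 calls dropped to 0 without RF_Co_primtrig replicate 2, without SF_Co_none replicate 1, or on the median-centred scale. Without RF_Co_primtrig replicate 2 the adjusted p of each was 0.0626, with differences of -8.06 for LDO, -7.95 for TAN, -5.81 for LACP1, -4.81 for 13LOX3 and a smaller -3.83 for AOC. Without SF_Co_none replicate 1 the differences were -6.53 (LDO) to -4.78 (LACP1), and on the median-centred scale -5.40 (LDO) to -2.47 (13LOX3).

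No gene differed detectably between leaves attacked in both cycles and leaves attacked in the second cycle only, averaged over strata. Against second-cycle damage only, HPL4 and HPL2 were each 0.95 higher (SE 0.651 and 0.655) and FAR5 differed by -0.38. The list members with the largest changes were PRX1 1.57 (7 of 9 replicates, tables in disagreement), FAR2 -0.97, NCED2 0.89, 13LOX3 -0.82, FLAVO1 0.81, GRAS2 0.62, GIB2 0.47, SOD -0.34, SA 0.34, HEX 0.33 and ETH 0.29. Their adjusted p were 0.945, or 0.978 for GIB2. In limma 0 genes passed, with 1 at an unadjusted p under 0.05, and 0 lists passed fry (smallest FDR 0.874). The direct test of a combined effect beyond the sum of both attacks had 0 genes in limma, 2 at an unadjusted p under 0.05, and a smallest adjusted p of 0.397. On the median-centred scale, where values were 0.523 lower, it also had 0.

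In RF_Co alone, 5 genes were lower after damage in both cycles than after second-cycle damage. The jasmonate enzymes 13LOX3, AOC and AOS fell by 4.38, 3.94 and 3.82, callose synthase CALI fell by 4.17 and the lyase HPL1 (Qrob_P0367910.2) fell by 2.92. The adjusted p ran from 0.0229 to 0.0268, 3 of 3 replicates were lower in each, and 4 jasmonate genes fell when adjusted over the list alone. All of these calls needed RF_Co_primtrig replicate 2. Without it the changes were smaller, -3.31 for 13LOX3, -2.24 for AOS, -1.67 for HPL1, -1.61 for CALI and -1.38 for AOC, and 0 genes passed, as without RF_Co_trig replicate 1 or replicate 2 and on the median-centred scale, and without RF_Co_trig replicate 3 there were 3. In SF_Co, SF_Pc and RF_Pc limma called 0 genes, with 0 at an unadjusted p under 0.05 in each, and 0 also in SF_Co with the replicate block.

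The response to second-cycle feeding was also read in leaves of plants damaged before, by comparing damage in both cycles with first-cycle damage only, a comparison added after the data were seen. FAR6, FAR5 and FAR4 rose by 3.33 ± 0.612, 3.33 ± 0.688 and 3.32 ± 0.691, each in 11 of 12 replicates. TAN rose by 3.25 ± 0.740 in 12 of 12 replicates, FAR2 by 2.72, HPL3 by 2.59 and HPL4 by 2.04. HPL2, HPL6, HPL5, NCED2, 13LOX3 and CHI_I rose by 1.87, 1.87, 1.86, 1.74, 1.69 and 1.49, in 8 to 11 of 12. The adjusted p ran from 0.000194 for FAR6 to 0.0426 for NCED2, and 0 genes fell. In the volatiles list 9 of 12 rose, 9 also adjusted over the list alone (fry FDR 2.17e-06). On the median-centred scale the volatiles FDR was 0.254, and auxin and gibberellin (0.0269) and defence proteins (0.0486, 11 of 14 lower) passed fry as lower instead. On the median-centred scale changes were 1.10 lower, which kept TAN (2.15) as the only higher call and made THAU1 (-1.31) and GLU1 (-1.57) as lower. Without RF_Co_primtrig replicate 2 there were 8 calls, and also 8 with technical replicates kept. In a fit of the contrast's own groups there were 6, and without replicate 1, 2 or 3 of each group there were 3, 6 and 27.

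Leaves of inoculated plants had lower levels of the farnesene synthases FAR1 and FAR3 relative to 18S, with calls that depended on the reference and on single replicates. FAR1 (Qrob_P0119200.2) fell by 1.67 ± 0.430 and FAR3 (Qrob_P0119240.2) fell by 1.66 ± 0.428 on average over 8 pairs of groups, from -7.03 and -6.94 in uninoculated plants. Both were lower in all 8 pairs and in 20 of 24 inoculated replicates (adjusted p 0.0127). Read noise could not separate these assays, so they count as 1 observation. Of the 64 genes 0 rose, and 2 volatiles genes fell adjusted over the list alone, with no list passing fry (smallest FDR 0.208). Without replicate 1, or without replicate 2, of each group 0 genes passed. Against the panel median in place of 18S, changes were 0.647 higher (16 higher and 48 lower became 41 and 23). FAR1 and FAR3 stayed lower there without passing (-1.02 and -1.01, adjusted p 0.221), while SDR2 (1.09), HEX (0.62), CHI_I (1.11), P450 (0.91) and CHI_II (0.74) passed as higher. In undamaged leaves alone limma called 0 genes at shoot flush and 0 at root flush, with 0 at an unadjusted p under 0.05 in each.

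Growth stage gave the most calls of the comparisons made. PR10 (comp21061_c0_seq1), a pathogenesis-related protein, fell by 8.59 ± 1.01 from shoot flush to root flush, 385-fold, in the average over 8 pairs of groups. That comparison was added after the data were seen. By group means, PR10 changed least in uninoculated plants after second-cycle damage (-7.81 to -9.75) and without damage (-8.00 to -10.36). It changed most in inoculated plants after first-cycle damage (-4.17 to -17.67), so the average covers unequal pairs. The laccases LACP2 (-7.61 ± 0.745) and LDO (-6.89) and the peroxidase PLP (-7.34) fell, and so did GIB2 (-6.53), LAC14_2 (-5.74), LAC14_1 (-5.52), PRP1 (-5.44), LAC14_3 (-4.98), THAU2 (-4.94), PRX2 (-4.79), TAN (-4.57), GLU1 (-4.51) and LACP1 (-4.10). FLAVO1, THAU1, MAD2, NCED3, P450, PRT, PRX5, PER31, NCED2 and IAA3 fell by 3.86, 3.67, 3.65, 3.47, 3.38, 3.38, 3.12, 2.94, 2.83 and 2.65. The farnesene synthase FAR6 rose by 2.44 ± 0.432. These 25 genes had adjusted p of 3.46e-11 to 4.12e-06 and moved that way in all 8 pairs and in 19 of 23 (FLAVO1) to 22 of 22 (PLP) measured root flush replicates.

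Relative to 18S, 59 of 64 genes passed, 11 higher and 48 lower at root flush. The higher ones included FAR2 (2.72), 10 of the 12 volatiles genes in all and CHI_I (0.96), while 5 of 5 jasmonate genes, 12 of 14 defence proteins and 6 of 6 laccases were lower. On the median-centred scale the laccases and 10 defence proteins passed as lower, but all 5 jasmonate genes were higher, with calls for AOS (1.15), AOC (1.11) and 13LOX5 (0.55). Adjusted over the list alone and relative to 18S, 10 volatiles genes were higher and 1 lower, 5 jasmonate genes lower, and 12 defence proteins lower and 1 higher. After centring on the panel median, which raised changes by 2.43, 34 genes were higher and 22 lower with a call, 11 and 22 of the calls relative to 18S kept their direction, and 18, among them HPL1, PAL and SOD, passed in the opposite direction, so the direction of those genes depends on the reference. In undamaged, uninoculated leaves alone, the planned comparison, limma called 0 genes with 5 at an unadjusted p under 0.05. FAR4, FAR5 and FAR6 passed there as higher at root flush without RF_Co_none replicate 1.

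**Figure D3:**
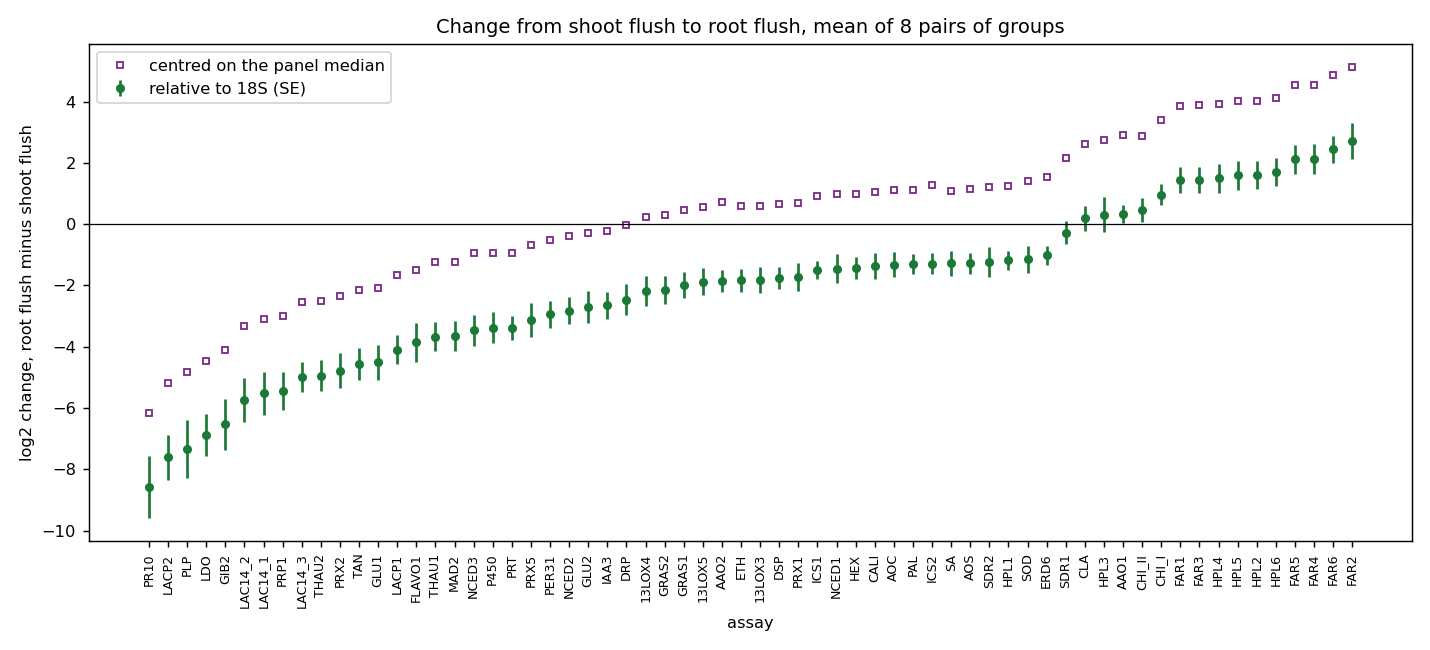
Log2 change from shoot flush to root flush of each assay, as a mean over 8 pairs of groups, relative to 18S (filled, bars give the SE) and centred on the panel median (open squares). Centring raised the changes by 2.43, with PR10 lowest at -8.59 and FAR2 highest at 2.72 relative to 18S.

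The authors' deposited table gave 910 fold changes over the undamaged, uninoculated group of the same stage, as ratios of arithmetic means. Ratios of geometric means, which match the log2 changes used above, differed over 2-fold from the authors' deposited table for 225 of the 910 and pointed the other way for 105. For SDR1 in RF_Co_primtrig the authors' deposited table gave 34.76, against 4.145 from geometric means of the same values, where RF_Co_primtrig replicate 2 weighs less.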

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

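All tests of explanations in this part were chosen after the results were seen, and the thresholds that decided them were set then too.

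In uninoculated plants, 5 genes responded differently to damage in both cycles at root flush than at shoot flush, by limma's interaction test. TAN changed by -1.16 at root flush and 6.25 at shoot flush, a difference of -7.41 ± 2.10, and AOC by -2.72 and 3.68, a difference of -6.39 ± 1.66. LDO, LACP1 and 13LOX3 differed by -8.80, -6.03 and -5.87. Of 24 interaction contrasts examined this was the only 1 with a call. The count was 0 without RF_Co_primtrig replicate 2, 0 without SF_Co_none replicate 1 and 0 after centring on the panel median. Without RF_Co_primtrig replicate 2 the log2 differences were -7.95 for TAN, -8.06 for LDO, -5.81 for LACP1 and -4.81 for 13LOX3, each with an adjusted p of 0.0626. AOC shrank to -3.83, since its change at root flush became -0.15, so the size given for AOC rests on that replicate. After centring, TAN and LDO differed by -4.01 and -5.40 and AOC by -2.99.

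The 18S Ct, which the comparisons did not use as a measurement, was 9.44 cycles in RF_Co_primtrig replicate 2, above the highest value of 5.99 among the undamaged, uninoculated samples and among the other 47 samples. Relative to 18S its PR10 level was 13.16 higher on the log2 scale than the mean of the other replicates of its group. Those replicates had an 18S Ct of 4.32 and 4.315. A later 18S Ct raises every level relative to 18S alike, so part of the 13.16 comes from the reference. Of its 130 reactions 16 were empty. A late 18S reading alone, or less template with the same effect on every assay, would shift all assays alike. Yet its best correlation over assays with any other sample was 0.279, against at least 0.910 for every other sample. Less template that affected assays unequally is not covered by this correlation, and some of its reactions were empty. An exchange with another sample of the series was argued against by 0 samples that correlated over 0.9 with it. Random failure of single reactions was argued against by its technical reads, which differed with an SD of 0.292 cycles while its distance from its group had an SD of 4.14. Less template with unequal effects on assays, a degraded or different template, or a sample from outside the series might explain it and stays open. No biological explanation was tested.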

How the results depend on the processing

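The choices that left out RF_Co_primtrig replicate 2, SF_Co_none replicate 1 or PRX1, blocked SF_Co alone or centred on the median of all measured assays were made after the data were seen, as were the comparisons of second-cycle damage after priming and of the stages over 8 pairs. Of the 30 summary results, 29 kept their side of the threshold, within 1.5-fold, with complete assays only, 29 with the replicate block, 29 without PRX1, 28 without RF_Co_primtrig replicate 2, 30 with missing values at the floor and 27 in fits of the contrast's own groups. Of the settings counted in this way the reference changed the most. With the global median of the complete assays 19 results were kept and 5 reversed. Those 19 had no calls on either reference, and none of the results with calls was kept. Most of the 30 results had no calls, so the counts above are mostly of results that stayed without any. Leaving out replicates was not ranked here, and its ranges are given below. The cause was not tested unless stated.

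Second-cycle against no damage in SF_Co, 0 calls relative to 18S, had 2 with complete assays only, 2 with the replicate block, 4 with technical replicates kept, 2 without PRX1, 4 with the SF_Co groups blocked alone, and 0 to 3 leaving out a replicate. In RF_Pc it had 2 with the global median. Averaged over strata, its 9 calls became 10 with the global median (2 higher, 8 lower), 5 with the median of all measured assays (2 higher, 3 lower), 5 with technical replicates kept and 0 to 6 leaving out replicates. The volatiles list, called in 1 list of 7, gave way to 1 other list moving down (auxin and gibberellin) with the global median, to 0 lists with technical replicates kept and to 0 with the median of all measured assays.

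First-cycle damage only had 0 to 42 calls in RF_Co and 0 to 14 averaged over strata leaving out replicates. Damage in both cycles against none in SF_Co (15 calls) had 2 with the global median, 4 in its own groups and 0 to 17 leaving out a replicate. A fit of its own groups uses fewer samples and only their own spread. That spread was large in SF_Co_none, with an SD of 6.447 for MCO, 4.399 for LDO and 3.17 for TAN. Which of these lowered the count was not tested. It had 0 to 1 in SF_Pc and 0 to 5 in RF_Co leaving out a replicate, and 1 in RF_Pc with the global median. Averaged over strata it had 14 with the global median, 15 with the median of all measured assays and 5 to 10 leaving out replicates.

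The 5 calls of damage in both cycles against second-cycle damage in RF_Co became 0 with the global median, 0 in its own groups, 0 without RF_Co_primtrig replicate 2 and 0 to 6 leaving out a replicate. The 2 lower genes of the inoculation contrast became 5 higher ones with the global median, 0 with the median of all measured assays and 0 to 2 leaving out replicates. Stage in undamaged Co had 0 to 3 leaving out a replicate. The interaction of inoculation and second-cycle damage had 1 with the global median and 1 with the median of all measured assays. Second-cycle damage after priming (13) had 3 with the global median (1 higher, 2 lower), 2 with the median of all measured assays, 6 in its own groups, 8 with technical replicates kept, 8 without RF_Co_primtrig replicate 2 and 3 to 27 leaving out replicates. Stage over 8 pairs (59) had 56 with the global median and 56 with the median of all measured assays, each with more genes higher than lower. With geometric means, 17 of 910 fold changes lay within 1% of the authors' deposited table.

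Of 31 sign changes among named genes outside the stage comparison, 2 concerned genes with a call, CHI_I (-0.0092) and PAL (-0.13) for damage in both cycles in SF_Co with the global median. The other 29 were in genes without a call, averaged over strata. With the global median and then the median of all measured assays, these were HEX -0.46 and -0.42 after second-cycle damage, IAA3 0.26 and 0.26 and PAL 0.19 and 0.19 after first-cycle damage, and SA -0.22 and -0.17, ETH -0.41 and -0.36 and HEX -0.23 and -0.18 after damage in both. PRX1 was at -0.0050 there with missing values at the floor. Without RF_Co_primtrig replicate 2, SA (-0.12) and ETH (-0.025) turned against undamaged leaves and SA (-0.24) against second-cycle damage. Leaving out replicates, second-cycle damage gave -0.43 to 0.50 for HEX, -0.84 to 0.23 for ICS2, -0.27 to 0.41 for ETH, -0.60 to 0.12 for IAA3 and -0.97 to 0.46 for SOD, and first-cycle damage -0.69 to 0.22 for IAA3. Damage in both against second-cycle damage gave -0.57 to 0.81 for SA, -0.31 to 0.76 for ETH, -0.26 to 0.89 for GIB2, -0.31 to 1.42 for FLAVO1, -0.14 to 1.22 for GRAS2 and -0.14 to 0.57 for HEX.

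The spread between replicates limited detection, by an amount that depended on the reference. Relative to 18S the median SE of a change was 1.31 in 1 stratum, 0.654 over 4 strata and 0.462 over 8 pairs. On the median-centred scale it was 0.928 in SF_Co, 0.464 over 4 strata and 0.327 over 8 pairs. Technical noise over assays was 0.131 cycles. That SD leaves out the offset between the 2 reads of a sample, whose median over assays ran from -0.29 to 1.35 cycles.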

Other observations

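All tests of splits and explanations in this part were chosen after the results were seen, and the bounds that decided them were set then too.

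For each comparison, other splits of the same samples were tested with limma for as many calls, the real split included. Second-cycle damage averaged over strata (9 calls) was reached by 1 of 100 splits, the highest other split giving 6. Damage in both cycles (9 calls) was reached by 4 of 100 splits, highest other 32. Second-cycle damage after priming (13 calls) was reached by 2 of 100, highest other 24. Stage over 8 pairs (59 calls) was reached by 1 of 100, highest other 38. For fry after second-cycle damage, the count of 1 passing list, of whichever kind, was reached by 3 of 100, highest other 2. These shares lay under 0.05, while inoculation over 8 pairs (2 calls) was reached by 6 of 100 splits, highest other 24. The splits were random draws, no correction was made for the number of results, and 4 and 6 of 100 cannot be told apart. A low share makes chance a less likely source of the calls, without excluding it. For results of 0 calls any split gives at least as many, so their counts of 100 of 100, or 10 of 10 within a stratum, carry no information on chance. Those over strata were first-cycle damage (highest other 49), damage in both against second-cycle damage (0), the interaction of both attacks (36), of inoculation and damage (4) and of stage and damage (12). Within a stratum 3 against 3 samples allow 10 splits, too few for a share under 0.05. Of those, 1 reached the 15 calls of damage in both cycles in SF_Co (highest other 0) and 1 the 5 of damage in both against second-cycle damage in RF_Co (highest other 2). Each remaining single-stratum comparison, including inoculation and stage in undamaged leaves, had 0 calls. In those the highest other split gave 29 for inoculation at shoot flush, 23 for stage, 24, 41 and 7 for first-cycle damage in SF_Co, RF_Co and RF_Pc, 5 for damage in both cycles in RF_Co and 0 elsewhere. Within a stratum, splits with many calls where the real split gave 0 point to a structure of the samples other than the groups. The splits for the stage interaction mixed shoot flush with root flush samples, and those for both attacks mixed all 4 treatments. Random stage splits can partly match the real split. Many calls in these splits can therefore come from the groups themselves.

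Replicates of the same group differed along an axis that resembled the stage change, and whether it underlies the splits with many calls was not tested. Within groups, over 47 samples without RF_Co_primtrig replicate 2, a single axis held 61.8% of the sum of squares. Its weights correlated with the change from shoot flush to root flush over 54 assays (r -0.971, rho -0.97), beyond the largest absolute r of 0.46 in 1000 permutations of the assays, which are not independent replicates. Measured within each stratum against the stage change of the other inoculation, r was -0.882 in SF_Co, -0.894 in SF_Pc, -0.821 in RF_Co and -0.53 in RF_Pc. As a hypothesis, replicates of the same group may have been at different points between the flushes, which the -0.971 is consistent with and which the labels cannot resolve.

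Scaling or input shared by all assays is argued against as the whole cause of this spread, since 62.2% of the within-group sum of squares stayed after centring each sample, while centring removed the rest. The stage difference itself was weighed the same way. The 18S Ct differed between stages by -0.12 cycles (SE 0.17) against 2.42 cycles for the median Ct of the panel, which argues against the 18S scaling as its whole cause. Less leaf RNA in all assays alike is argued against as the whole cause by 56 genes that passed after centring on the median, 34 higher and 22 lower. A changed share of ribosomal RNA would also move all assays alike, so the same 56 genes argue against it as the whole cause. It stays open for the shared shift of 2.43 between the scales, and leaf age and the stage itself stay open as untested.

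Some assays followed each other within read noise over the 48 samples. The difference between assays had an SD of 0.049 for FAR1 and FAR3 and 0.054 for FAR4 and FAR5, against a median of 2.41 over 2080 pairs. Read noise was taken as 0.089, a robust spread (scaled median absolute deviation) of the difference between 2 single reads of the same assay, less the sample's offset. The assay values were means of 2 reads, which vary less than single reads, so this bound is lenient. These 2 pairs lay under read noise, which is consistent with both assays reading 1 template, as near-identical gene copies might. LAC14_3 and THAU2, described as a laccase and a thaumatin-like protein, differed by an SD of 0.089, and shared regulation of separate templates cannot be told apart there from a shared template, since no primer sequences were used here. In all 9 pairs lay under 0.3, among them every pair of HPL2, HPL4, HPL5 and HPL6.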
